A study of Mus musculus with 2 samples.

How the data were processed

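H3K9ac ChIP-seq peak lists of mouse neural tube at embryonic day 13.5 were analysed, from 1 group of 2 replicates that the labels call biological. The labels describe tissue pooled over male and female embryos. Per the labels and the deposited descriptions, each replicate's list was made from that replicate's alignments and 1 control file, the pooled list from both alignments and 2 control files, and the replicated list from those 3 lists. The aligner, the peak caller and its thresholds are not given in the sources used here. Neither is the rule that makes a peak replicated, and 8490 replicated peaks overlapped peaks of fewer than both replicates by 50% of either peak. The control reads were not analysed, since only peak lists were used. Read depth per sample is unknown, so no limit of detection can be given, and Wilson intervals cover counting error over genes or peaks only.

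The deposited signal value of a peak is the enrichment over the control that the authors' caller wrote, and it was compared within a list only. The deposited −log10 p and −log10 q values are per peak against the control, the second adjusted within its list by the authors. The −log10 q value was used for a stricter threshold of 2 and the −log10 p value for ranking peaks when lists were cut to the same number. The deposited score and summit position of each peak entered no result. In the deposited lists 76.0% of replicate 1's peaks, 77.7% of replicate 2's, 85.4% of pooled peaks and 98.9% of replicated peaks had a −log10 q of at least 2. Coordinates are on mm10 and are given from 1.

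Genes came from the GENCODE M21 annotation, and the sequence of the same build gave base composition. The 21911 protein-coding genes on chromosomes 1 to 19, X and Y were used, with a repeated symbol kept once. A gene was called marked when a replicated peak overlapped the window of 1 kb on each side of any of its annotated TSSs. Its signal value was the highest among those peaks. A TSS window was called CpG-rich with an observed over expected CpG ratio of at least 0.6 and a GC content of at least 50%. Domains were replicated peaks joined across gaps of up to 1 kb, and a gene's domain was the widest over its TSS windows. Of the marked genes, 3027 shared a domain with another marked gene, and 3652 genes shared a TSS window with another gene.

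Peaks of the replicates were paired when 50% of a peak was overlapped by the other list, and tested against 1000 circular shifts along each chromosome, one-sided. Genomic classes were set by peak midpoint in the order TSS window, other exon, intron and intergenic. They were tested against the same number of shifts, one-sided in the direction of the difference seen. TSSs, exons and introns here were those of the 55413 annotated genes of any type. Alternatives used 100 shifts, whose smallest p is 0.0099. The 29 gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists fixed by name were neural progenitor, pan-neuronal, proneural, dorsal and ventral patterning, spinal subtype, forebrain and midbrain, 3 Hox groups, neurotransmitter, Hedgehog, Notch, axon guidance, glial, neural crest, meninges, endothelial, erythroid, microglia, muscle, endoderm, skin, germline, synapse, S phase, housekeeping, ribosomal protein and olfactory receptor genes. They were written from general knowledge and hold genes of several tissues each. Domain widths of lists with at least 5 marked genes were compared with 10000 random lists of marked genes, two-sided. For the classes of neural tube and other tissue genes, Tal1 and Zic1 belonged to both and were left out. Ahsp and Amy2b had no annotated gene of that symbol. Peaks on scaffolds outside the main chromosomes were left out (14, 13, 14 and 11 in the replicate 1, replicate 2, pooled and replicated lists).

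The gene lists, the tests of the report and the named-gene rule were fixed before the data were examined, and the closing section names the tests chosen later. The rule named the 10 genes with the widest domains, the 10 with the highest signal values, up to 4 marked members with the highest values and up to 4 unmarked members of each list (or the whole smaller class when it held 5 or fewer), the 3 strongest unmatched peaks of each replicate and all Hox genes. Domains beyond these, the distal peaks, the tissue examples of the class comparison and the examples of gene calls were chosen after their values were seen.

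Alternatives changed the overlap, the peak threshold, the number of peaks per list, the TSS window (500 bp or 2 kb), the TSSs used, the peak list, the joining gap (3 kb or touching peaks only) and the genes (CpG-rich only), and left out each replicate in turn. Kinds of alternative added after seeing the data were replicated peaks that overlap both replicates' own peaks, genes sharing a TSS window left out, and each domain counted once.

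The code was tested on simulated data. With 60% of 5000 peaks planted as shared, 60.0% were recovered, and 1 of 20 simulated pairs of independent lists had p under 0.05. Among lists of 20 genes out of 20000, 100% of those planted as marked more often were called, 95.6% of those planted as less often and 2.78% of those with no difference. The planted shares were large differences, 98% and 25% marked against 66% of other genes. Smaller differences were not simulated, so these rates do not cover them. Lists with 2-fold wider domains were called in 68.9% of cases, and lists with no width difference in 1.67%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and the random seed was 20.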

Results

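Acetylation of histone H3 at lysine 9 (H3K9ac), a mark found mainly at active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the neural tube of mouse embryos at embryonic day 13.5. The labels describe B6NCrl embryos pooled over both sexes and give 1 group of 2 biological replicates. The values analysed were peak lists on the mm10 build: 1 list per replicate, 1 list called from the pooled reads, and 1 list of peaks called replicated. On chromosomes 1 to 19, X and Y, replicate 1 had 85147 peaks and replicate 2 had 73414 peaks. The pooled list had 103514 peaks there and the replicated list had 46856 peaks. The replicated peaks had a median width of 658 bp and covered 48.3 Mb, or 1.77% of the sequenced bases. Each peak carries the authors' signal value, which can be ranked within a list but not set against another list. The read depth of the replicates is unknown, since peak lists hold no read totals. With 1 group there was no comparison between conditions, so the questions were which genes carried the mark, how wide it was, where it lay and how far the replicates gave the same peaks. Each p-value was computed over genes or peaks, not over embryos.

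Most protein-coding genes carried H3K9ac at a transcription start site (TSS). The gene with the highest signal value of a replicated peak was Mex3b on chromosome 7, an RNA-binding protein gene, followed by Brsk1, a neuronal kinase gene. Bicral, the histone methyltransferase gene Setd1b, Rhof and Skida1 came next, with Hoxb3, Hoxb4, Hoxb5 and Hoxb6 behind them under a shared peak. Mex3b had a signal value of 48.5 in the replicated list, with 44.7 and 43.3 in the lists of replicates 1 and 2. Brsk1 had 47.8, with 40.3 and 41.0 in the replicates' own lists. Rhof shared its 46.7 peak with Setd1b, and Rhof's own TSS window reached only 7.87 and 6.55 in the replicates. A replicated peak lay within 1 kb of an annotated TSS in 14534 of 21911 protein-coding genes, or 66.3% (95% Wilson interval 65.7 to 67.0). The replicates' own lists gave 67.8% and 67.4%, a mean of 67.6% ± 0.297 (SD, n = 2). Genes with a CpG-rich TSS window were marked in 99.0% of cases (7436 of 7512). Genes with other TSS windows were marked in 49.3% of cases (7098 of 14399). Intervals cover counting error only.

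Genes of the neural tube's own cells were mostly marked. Every listed gene of neural progenitors, of neurons in general, of the proneural basic helix-loop-helix class and of dorsal patterning carried a replicated peak, as did every listed gene of the Notch and Hedgehog pathways and of axon guidance. Among progenitor genes Sox11 and Msi1 had the highest signal values, with Vim and Hes5 behind them. Elavl3 and Tubb3 led the pan-neuronal genes, ahead of Nhlh2 and Rbfox3. Hes6 and Ascl1 led the proneural list, which also holds Olig1 and Olig2, ahead of Neurod2 and Neurog2. Dorsal patterning was led by Zic1 and Zic4, which share a peak, and by Zic2 and Zic5. Ptch1, the Hedgehog receptor gene, stood above Boc, Cdon and Smo. Maml1, Rbpj, Hes5 and Notch1 led the Notch genes, and Plxna2, Ephb2, Plxna1 and Efnb3 led axon guidance.

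Sox11 had a signal value of 41.9 in the replicated list, with 39.3 and 36.5 in replicates 1 and 2. Msi1 had 36.5, with 30.1 and 33.4 in the replicates. Elavl3 had 31.8 (replicates 26.1 and 27.8) and Tubb3 31.4 (34.4 and 24.2). Ascl1 reached 16.9 (15.8 and 12.3) and Neurog2 8.26 (9.50 and 6.11). Ptch1 had 30.6 (27.6 and 27.8), and Plxna2 had 32.5 (36.8 and 22.8). All 16 progenitor genes were marked, against 66.3% of other genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 29 lists, p = 0.00471). The same test gave p = 0.00133 for the 20 pan-neuronal genes and p = 0.00697 for the 14 proneural genes in Fisher's exact test. For the 17 dorsal patterning genes and the 17 Notch genes the adjusted exact p was 0.00316 each. The 12 Hedgehog genes gave an adjusted exact p of 0.0174 and the 32 axon guidance genes 1.94e-05. Both replicates' own lists marked the whole of each of these lists. CpG-rich promoters limit this comparison: among genes with a CpG-rich TSS window 0 of 28 lists were marked more often, and 0 were at an unadjusted p under 0.05 in Fisher's exact test, since 99.0% of all such genes were marked.

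Transcription factors of spinal neuron subtypes were marked in 30 of 33 cases. Foxp1, a motor column gene, had the highest value in this list, followed by the dorsal horn gene Lbx1 and by Lhx5 and Lhx1. Evx1, Vsx2 and Wt1 were the unmarked members. In ventral patterning Irx3, Nkx6-1, Irx5 and Prdm12 had the highest values of the 11 marked genes, and Arx, Dbx1, Foxn4 and Nkx2-9 were unmarked. Transmitter genes of excitatory (Slc17a6), inhibitory (Slc32a1, Gad1) and glycinergic (Slc6a5) neurons were marked, and Slc17a8 and Tph2 were not. Foxp1 had a signal value of 28.5 (replicates 29.7 and 21.6) and Lbx1 22.6 (24.2 and 18.1). Slc17a6 had 17.7 (18.8 and 12.9). The spinal subtype list was marked more often than other genes (90.9%, adjusted exact p = 0.00343). It lost that call when only the 5′ end of each gene was used (78.8%). The ventral list (11 of 15, adjusted exact p = 0.832) and the transmitter list (16 of 18, adjusted exact p = 0.0670) were not called. In each replicate's own list the transmitter genes were called, at 94.4%, as they were in the pooled list. When only the 5′ end of each gene was used, 13 of 18 transmitter genes were marked.

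Genes of the anterior brain were marked in part. Emx2, Eomes, Fezf1 and Fezf2, all forebrain regulators, carried no replicated peak. Satb2 and Foxd1 had the highest values of the marked members, then Dlx2 and Lhx8. Only 13 of 26 forebrain and midbrain transcription factors were marked, which was not called against other genes (adjusted exact p = 0.123). With the pooled list 17 of 26 were marked, at 65.4%, and with the 5′ end only the list was marked less often, at 38.5%. Among genes with a CpG-rich TSS window the list was marked less often, at 11 of 22 (adjusted exact p = 9.69e-16). Satb2 had a signal value of 9.68 (replicates 6.93 and 7.93) from a TSS away from its 5′ end. Dlx2 had 5.17 (5.77 and 4.06).

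All listed genes of mature nerve cells and of general cell functions were marked. Vamp2 and Dlg4, genes of the synapse, led the mature synapse and ion channel list with Kcnc1 and Scn8a. The cell cycle genes Cdk4, Aurka, Birc5 and Mcm5 led the S phase and mitosis list. Actb and Ywhaz led the housekeeping list, ahead of Tubb5 and Eef1a1. Rps14, Rps17, Rps15 and Rps7 led the ribosomal protein genes. Vamp2 had a signal value of 34.9 (replicates 37.2 and 26.8), Cdk4 29.0 (23.7 and 26.5) and Actb 43.8 (37.8 and 39.7). The lists were marked in 29 of 29, 28 of 28, 25 of 25 and 77 of 77 genes. Their adjusted exact p-values were 4.46e-05, 7.01e-05, 0.000170 and 4.51e-13 in that order.

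Genes of other cells that lie in or beside the neural tube were mixed. Of maturing glia, Slc1a2, Mbp, Cnp and Ugt8a were marked, and Gfap, Mag, Mobp and Mog were not. Ntrk2, Mpz, Ntrk3 and Ngfr led the neural crest and sensory genes, whose unmarked members were Dbh, Hand2 and Phox2b. The meningeal genes Zic1, Foxc1, Crabp2 and Pdgfrb were marked, and Col3a1, Lum and Rgs5 were not. Zic1 is also in the dorsal patterning list, so its mark need not come from meninges. In endothelium Kdr, Fli1, Mfsd2a and Ets1 were marked, and Cdh5, Robo4, Slco1c1, Tek and Tie1 were not. Slc1a2 had a signal value of 23.8 (replicates 23.8 and 18.8) and Kdr 9.71 (12.3 and 8.50). None of these lists was called: 13 of 20 glial genes (adjusted exact p = 1), 17 of 20 crest genes (0.123), 14 of 17 meningeal genes (0.247) and 13 of 18 endothelial genes (0.832). Crest genes were called more often in each replicate's own list (90.0%), and meningeal genes in the pooled list (94.1%). When only the 5′ end was used, 14 of 20 crest genes were marked.

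Genes of blood, microglia, inner organs and germ cells were mostly unmarked. The globin gene Hba-a1 and Alas2, Ermap and Gata1 carried no replicated peak, and Klf1, Nfe2, Gypa, Epor and Tal1 were the marked erythroid genes. Tal1 is also in the spinal subtype list. Hexb and Tmem119 were the marked microglial genes, and Aif1, C1qa, C1qb and C1qc were unmarked. Afp, Alb, Apoa1 and Apob of the liver were unmarked, and Sftpc, Foxa3, Cdx1 and Hnf1a were the marked endoderm genes. Dazl and Esrrb were marked, and Ddx4, Dppa2, Dppa3 and Dppa4 were not. Gypa had a signal value of 6.36 (replicates 7.70 and 4.52), and Tmem119 only 2.79 (2.94 and 2.69). Sftpc had 26.7 (25.9 and 22.6), at a TSS away from its 5′ end. Hnf1a's 2.47 peak had no counterpart at its TSS in either replicate's own list. The erythroid list was marked in 5 of 17 genes (less often than other genes, adjusted exact p = 0.00578). Microglial genes were marked in 2 of 20 cases (adjusted exact p = 1.95e-06), with 7 and 6 in the replicates' own lists. Endoderm genes were marked in 4 of 23 cases (1.13e-05, adjusted exact test) and germline genes in 2 of 22 (3.56e-07), with 4 and 3 in the replicates' own lists. Among genes with a CpG-rich TSS window, endoderm and germline genes (2 of 4 each) were still marked less often. The unmarked endoderm genes there were Cdx2 and Nkx2-1, and Nkx2-1 is also in the forebrain and midbrain list. The unmarked germline genes there were Ddx4 and Sycp1. The single erythroid gene with a CpG-rich TSS window was marked and the single such microglial gene was not, and neither list was called. All other genes of both lists lacked a CpG-rich TSS window, and 49.3% of all such protein-coding genes were marked. No test set the lists against such genes alone, so promoter class was not separated from tissue in these calls.

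Muscle and skin genes were not called. Mylpf, Runx2, Tbx6 and Tcf15 were the most strongly marked muscle, cartilage and somite genes, and Acta1, Actc1, Matn1 and Mb were unmarked (14 of 25, adjusted exact p = 0.340). Krt10, Krt1, Lor and Epcam led the skin list, and Cldn4, Dsg1a, Dsg3 and Flg were unmarked (9 of 20, adjusted exact p = 0.0783). Skin genes were marked less often with the 500 bp window (30.0%) and with the 5′ end only (35.0%). Olfactory receptor genes were marked in 2 of 1092 cases, Olfr94 and Olfr71, and receptors such as Olfr1 and Olfr10 were unmarked. Both were marked away from their 5′ ends, and the replicates' own lists marked 5 and 3 receptors. In all, 14 of 29 lists were marked more often than other genes, 5 were marked less often and 10 were not called.

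**Figure D1:**
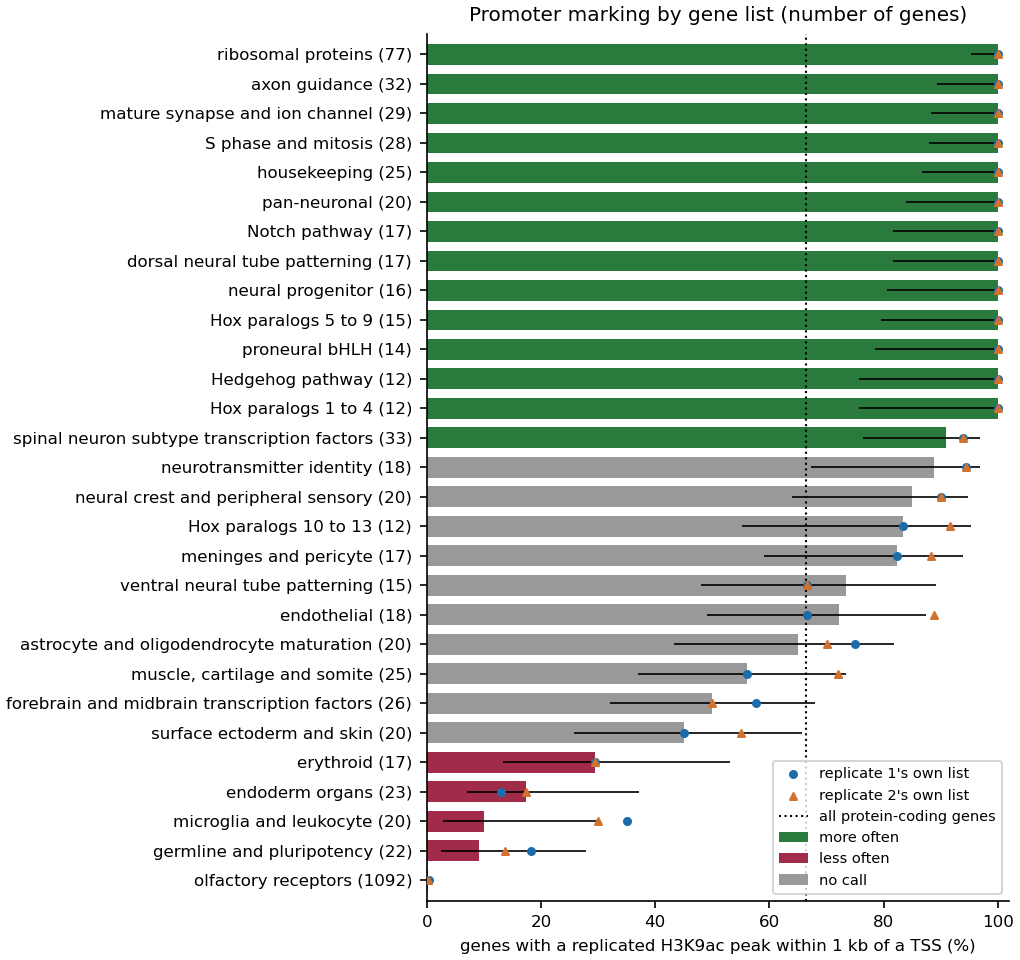
Share of each gene list with a replicated H3K9ac peak within 1 kb of an annotated TSS, in percent, with the number of genes in parentheses. Bars are the replicated list with 95% Wilson intervals, points are each replicate's own list and the dotted line is the 66.3% of all protein-coding genes. The 13 lists at 100% include neural progenitor, pan-neuronal and Notch genes and Hox groups 1 to 4 and 5 to 9, and the olfactory receptors lie at 0.183%.

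Taken as classes, neural tube genes stood above genes of other tissues. The first joined the progenitor, pan-neuronal, proneural, dorsal and ventral patterning, spinal subtype, neurotransmitter and axon guidance lists. The second joined the meninges, endothelial, erythroid, microglia, muscle, endoderm, skin and germline lists. Sox11, Elavl3, Ascl1 and Lbx1 stand for the first class, and the unmarked Alb, Dppa3, Flg and C1qa for the second. The meninges and endothelial lists were mostly marked (14 of 17, with Zic1, and 13 of 18). In the neural tube class 154 of 163 genes were marked (94.5%). In the other tissue class 61 of 160 genes were marked (38.1%). The difference was 56.4 percentage points (two-sided Fisher's exact test, p = 2.47e-29). Among genes with a CpG-rich TSS window the shares were 106 of 108 and 24 of 30 (exact p = 0.00138). Of the 61 marked genes of other tissues, 6 shared a TSS window with another gene and 10 were marked only away from their 5′ end.

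The Hox genes, which set position along the body axis, were marked nearly throughout their 4 clusters. Hoxa1 to Hoxa10, Hoxb2 to Hoxb9, Hoxc4 to Hoxc10 and Hoxd3 to Hoxd10 lay under a few long domains. The mark thinned towards the posterior genes: Hoxa11, Hoxc11 and Hoxd11 had domains of a few kilobases, Hoxc12 and Hoxc13 had weaker ones, Hoxb13 and Hoxd13 had small peaks, and Hoxa13 and Hoxd12 had none. In replicate 2's own list Hoxc11 and Hoxd11 joined long domains of 81304 and 63020 bp. At the other end Hoxb1 and Hoxd1 had small domains of their own. Forebrain and midbrain factors such as Emx2, Fezf2 and Eomes lacked the mark. Hoxb3 to Hoxb9 shared a peak with a signal value of 45.7 (replicates 44.7 and 33.3). Hoxd3 and Hoxd4 had 38.6 (40.0 and 27.4), and Hoxc6 had 32.3 (32.3 and 27.9). Hoxa11 had 8.36 (6.59 and 9.19), Hoxb1 7.28 (9.19 and 5.99) and Hoxd13 3.41 (2.99 and 3.28). All 27 Hox genes of paralog groups 1 to 9 were marked, against 13 of 26 forebrain and midbrain factors (two-sided Fisher's exact test, p = 1.24e-05). The 12 genes of groups 1 to 4 (adjusted exact p = 0.0174) and the 15 of groups 5 to 9 (0.00697, exact test) were called against other genes. The 10 of 12 in groups 10 to 13 were not (adjusted exact p = 0.401), but all 12 were marked and called in the pooled list. Neighbouring Hox genes share domains, and with each domain counted once the comparison was 7 of 7 against 13 of 26 (exact p = 0.0266).

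**Figure D2:**
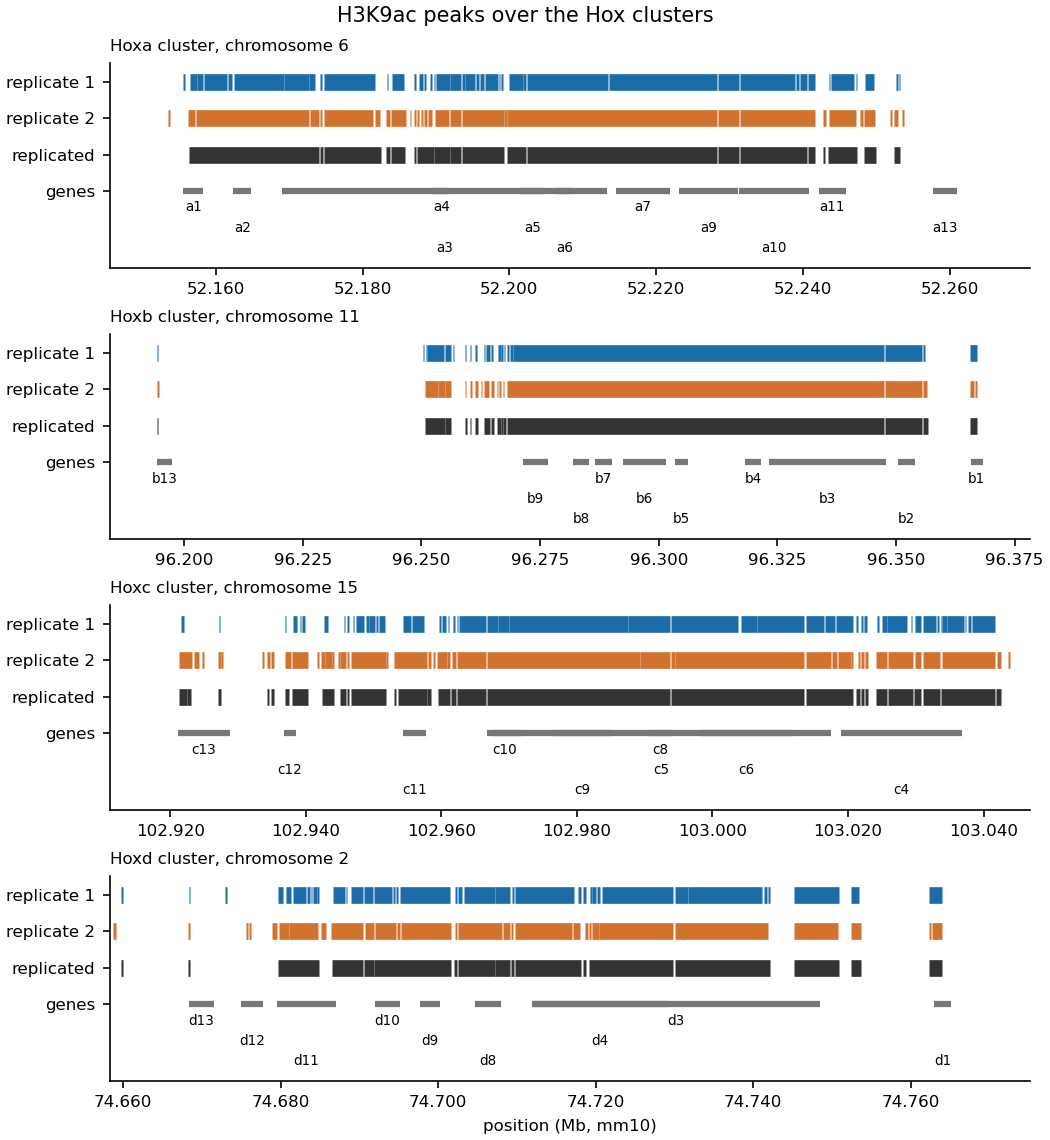
H3K9ac peaks over the 4 Hox clusters, by position in Mb on mm10, from replicate 1, replicate 2 and the replicated list, with protein-coding Hox genes as grey bars. Peaks run almost without gaps from Hoxb2 to Hoxb9, and Hoxa13 and Hoxd12 have no replicated peak at their TSS.

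The 4 widest domains lay over the Hox clusters. Domains were replicated peaks joined across gaps of up to 1 kb. In the replicated list the Hoxb2 to Hoxb9 domain was the widest, then the Hoxc4 to Hoxc10, Hoxd3 to Hoxd10 and Hoxa3 to Hoxa10 domains. A domain over Cirbp, Midn and neighbouring genes, the Zic1 and Zic4 domain and a further Hox domain over Hoxa1 to Hoxa3 came next. Domains over the transcription factor genes Ebf3, Nr2f2 and Zfhx3 followed. The transcription factor genes Lhx1, Meis2, Pou3f3, Nfib, Pax2, Lmx1b and Sox2 lay among the 25 widest, as did Notch1, Cxxc5, Irf2bpl, Bahcc1 and Lamp5. The Hoxb domain spanned 93539 bp (chromosome 11, 96263164 to 96356702). The Hoxc domain spanned 63474 bp (chromosome 15, 102959539 to 103023012) and the Hoxd domain 55693 bp (chromosome 2, 74686466 to 74742158). The Hoxa3 to Hoxa10 domain spanned 54566 bp (chromosome 6, 52186996 to 52241561). The Zic1 and Zic4 domain spanned 37969 bp (chromosome 9, 91349996 to 91387964), the Hoxa1 to Hoxa3 domain 29442 bp and the Ebf3 domain 27144 bp (chromosome 7, 137296186 to 137323329). In replicate 2's own list Hoxa1 to Hoxa10 lay in a single domain of 85330 bp, wider than those over Hoxc10 (81304 bp) and Hoxd10 (63020 bp). The Zic1 and Zic4 domain was narrower in the replicates' own lists (15995 and 25632 bp), as was that over Cirbp (24489 and 38942 bp). Lhx1 had 23431 bp, Notch1 21302 bp and Sox2 17992 bp. The median over marked genes was 2275 bp, and 186 marked genes lay in domains of at least 10 kb. No test compared the genes of these domains with other genes.

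Domain width set some lists of neural genes apart and not others. Sox11, Msi1 and Hes5 of the progenitors had domains of 9827, 11548 and 7125 bp. Tubb3 of the pan-neuronal list had 6183 bp, Ptch1 16825 bp, Lbx1 10699 bp and Slc17a6 13074 bp. The marked forebrain and midbrain genes had a narrow median, with 859 bp at Dlx2 and 805 bp at Lhx8. The test covers the median of the 13 marked members, not each gene. Skin genes had a narrow median as well, with 852 bp at Epcam. Against 10000 random lists of marked genes of equal size, 14 of 25 lists were wider and 2 were narrower (two-sided permutation test, Benjamini-Hochberg adjusted). The wider lists had these medians: 6922 bp for progenitors, 5530.5 bp for pan-neuronal genes, 4895.5 bp for spinal subtypes, 4880 bp for axon guidance, 4605 bp for Notch and 4155 bp for Hedgehog. Ventral patterning had 4362 bp, neural crest 4858 bp and neurotransmitter identity 3977 bp. Hox groups 1 to 4 had 55129.5 bp, groups 5 to 9 had 63474 bp and groups 10 to 13 had 4930.5 bp. Housekeeping (3158 bp) and ribosomal protein genes (2959 bp) were also wider. Marked genes with a CpG-rich TSS window had a median of 2823 bp against 1700.5 bp for others, and the random lists were not matched on this. Neurotransmitter identity was not called without replicate 1 (2276 bp), without replicate 2 (2718 bp), with the pooled list (2587.5 bp) or with peaks overlapping both replicates' own peaks (2943 bp). Neural crest was not called without replicate 1 (3228.5 bp), and Hox groups 10 to 13 were not called without replicate 2 (3474.5 bp). Hox groups 1 to 4 had 85330 bp without replicate 1. The Hox medians also moved with the joining gap: groups 1 to 4 and 5 to 9 had 11397.5 and 27126 bp with only touching peaks joined, and 96937 and 105902 bp across 3 kb. Groups 10 to 13 had 79731 bp across 3 kb. The forebrain and midbrain median was 805 bp (adjusted permutation p = 0.000625) and the skin median 1235 bp (adjusted permutation p = 0.0394). For progenitors the unadjusted permutation p was 0.0002, the smallest that 10000 random lists can give.

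No width call was made for 9 lists. Their medians were 2803 bp for dorsal patterning, 2120 bp for proneural genes, 2665 bp for synapse genes, 2268.5 bp for S phase genes and 1841 bp for glial genes. Meningeal genes had 1916 bp, endothelial genes 2035 bp, muscle genes 1552 bp and the 5 marked erythroid genes 1163 bp. With each domain counted once, 12 of 24 lists were wider and 1 was narrower, and neither neurotransmitter identity (2541 bp) nor skin was called. Hox groups 5 to 9 could not be tested that way, since their 15 genes lie in fewer than 5 domains. When only touching peaks were joined, 8 lists were wider, and ventral patterning (1847 bp), neural crest (2064 bp), spinal subtypes (2287.5 bp), neurotransmitter identity (2293 bp), Hedgehog (2416 bp), housekeeping (2223 bp) and ribosomal protein genes (2099 bp) were not called. Ventral patterning was also not called with peaks joined across 3 kb, nor housekeeping genes with the 5′ end only (2367 bp). Muscle genes were narrower in either replicate's own list (1359.5 and 1095.5 bp), with the 2 kb window (1356.5 bp) and with only touching peaks joined (1127.5 bp), and endothelial genes were narrower without replicate 1 (1437 bp). Dorsal patterning was wider with the pooled list (3980 bp) and across 3 kb (4697 bp), and synapse genes were wider with only touching peaks joined (2447 bp).

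**Figure D3:**
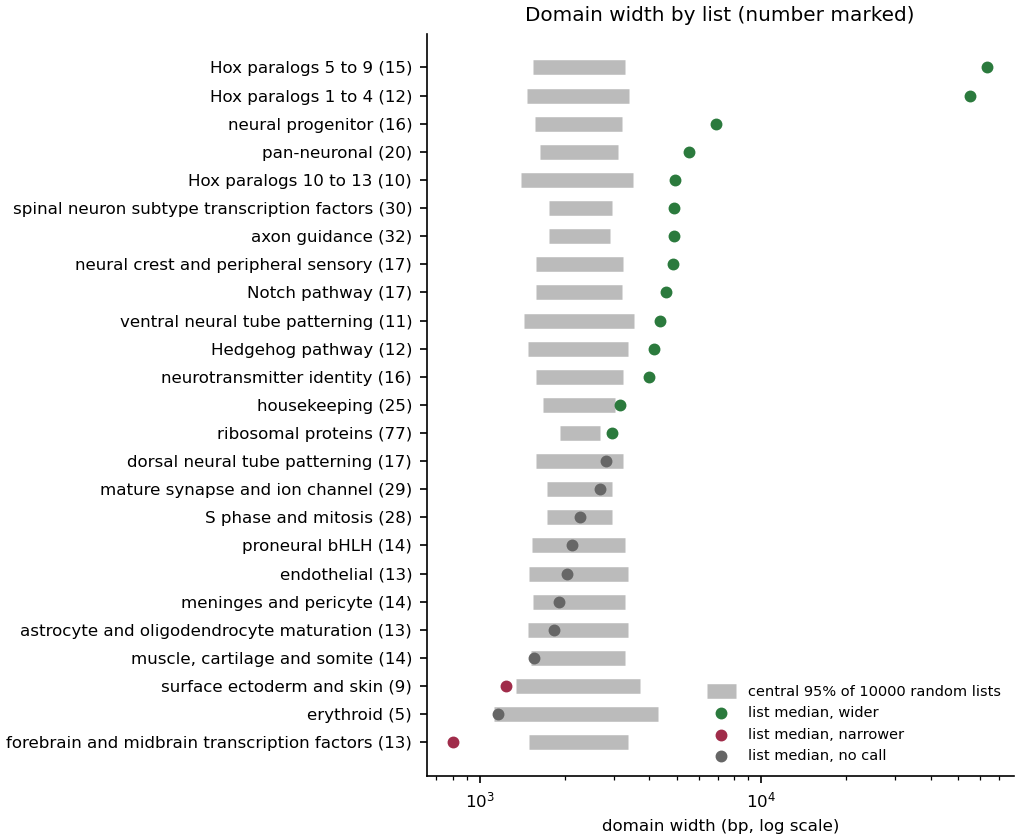
Median H3K9ac domain width of the marked genes of each list, in bp on a log axis, with the number of marked genes in parentheses. Points are list medians and grey bars hold the central 95% of 10000 random lists of equal size. Progenitor and pan-neuronal medians of 6922 and 5530.5 bp lie right of their bars, and the forebrain and midbrain median of 805 bp lies left of its bar.

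Replicated peaks gathered at promoters. Strong peaks away from any annotated TSS were found as well: the 5 strongest lay in the Lncppara region of chromosome 15, near Foxn2 on chromosome 17, near Ptma on chromosome 1, near Chd2 on chromosome 7 and over Gm12746 on chromosome 4. The Lncppara peak (85667157 to 85681828) was 14672 bp wide with a signal value of 35.5 (replicates 35.9 and 30.0). It lay 60.5 kb from the 5′ end of Ppara. The peak 184 kb from Foxn2 (88255505 to 88257717) had 29.1. The peak 38.4 kb from Ptma (86487735 to 86488852) had 26.6, and the peak 75.8 kb from Chd2 (73616753 to 73618461) had 25.8. The Gm12746 peak (106838805 to 106842099) had 25.5 and lay 35.5 kb from Acot11. Peaks over 5 kb from any TSS made up 31.5% of the list (14739) and had a median signal value of 3.17.

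By midpoint, 43.9% of replicated peaks (20586) lay within 1 kb of a TSS of any annotated gene, protein-coding or not. The mean after circular shifts along the chromosomes was 6.27%. Other exons held 5.43% (2546, shifted mean 3.35%), introns 33.8% (15815, shifted mean 39.4%) and intergenic sequence 16.9% (7909, shifted mean 51.0%). Each share lay beyond its shifts in a permutation test of 1000 shifts, one-sided in the direction seen (p = 0.001, the smallest they can give). The permutation p-values below are one-sided in the same way, and two-sided ones would be larger. The TSS share was lower, but above its shifts, in the pooled list (27.6%) and in the lists of replicates 1 and 2 (32.5% and 35.0%). The intron share was above its shifts in the pooled list (44.8%, permutation p = 0.0099, the smallest that 100 shifts can give) and in replicate 1's own list (41.5%, permutation p = 0.0198). The other exon share fell below its shifts when any overlap of 1 bp set the class (6.98% against a mean of 7.52%, permutation p = 0.0297). The intron share did not differ from its shifts in replicate 2's own list (39.9%, permutation p = 0.238) or with a 500 bp window (41.3%, permutation p = 0.356). The median signal value was 9.86 at TSS windows and 3.26 elsewhere in the replicated list. The median width was 1197 bp at TSS windows and 483 bp elsewhere.

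The replicates shared nearly all of their strong peaks and fewer of their weak ones. The strongest peaks that the other replicate did not touch lay in an intron of Ahcyl2, near Tmpo and near Ssx2ip in replicate 1. In replicate 2 they lay in an exon of Bcl10, in an intron of Gpm6b and near Blcap. The Ahcyl2 peak (chromosome 6, 29853084 to 29853353) had a signal value of 7.65, the peak 7.12 kb from Tmpo (chromosome 10, 91188158 to 91188704) 7.05 and the peak 66.6 kb from Ssx2ip (chromosome 3, 146337781 to 146338284) 6.43. The Bcl10 peak (chromosome 3, 145923675 to 145924002) and the Gpm6b peak (chromosome X, 166346483 to 166346822) had 6.18 each. The peak 42.7 kb from Blcap (chromosome 2, 157613842 to 157614204) had 5.67. In replicate 1, 39123 peaks (45.9%, 95% Wilson interval 45.6 to 46.3) had a partner overlapping at least 50% of the peak. In replicate 2, 37166 peaks (50.6%, 50.3 to 51.0) had one. Circular shifts gave a mean of 1.90% in each direction (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give).

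Split by signal value into 5 bins of equal size, 99.7% of replicate 1's strongest peaks and 99.9% of replicate 2's had a partner. In the weakest bin 21.4% and 23.3% had one. The top bin exceeded the bottom bin by 78.3 points in replicate 1 and 76.6 points in replicate 2 (mean 77.5 ± 1.15, SD over the 2 directions). Both come from 1 pair of lists, so this SD does not measure the spread between replicates. The rise was not even, since in replicate 1 the lowest share was in the next weakest bin (17.9%). Signal values of paired peaks had a Spearman's rho of 0.764 from replicate 1's peaks and 0.817 from replicate 2's, across peaks, which are not independent replicates.

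**Figure D4:**
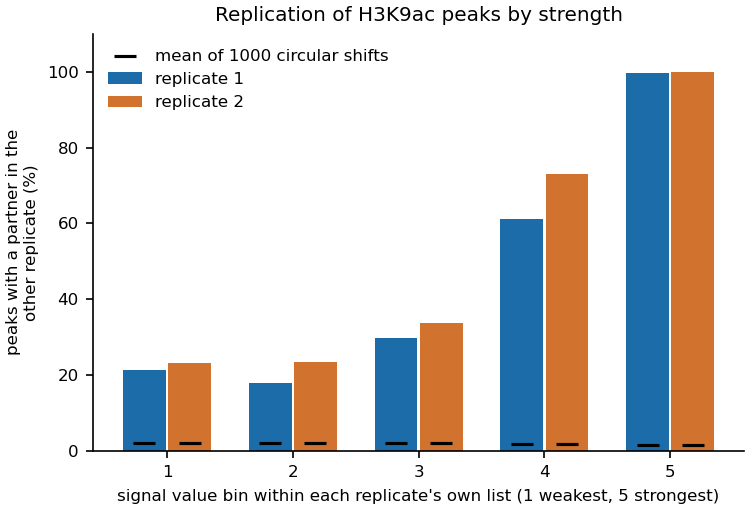
Share of peaks with a partner in the other replicate, in percent, by signal value bin within each replicate's own list, for replicate 1 and replicate 2. Bars are the observed shares and black lines the mean of 1000 circular shifts, and the strongest bins reach 99.7% and 99.9%.

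Gene calls differed little between the replicates. Sox11, Elavl3, Hoxb4 and Actb were marked in both replicates' own lists. Evx1 and Cdh5 were marked in replicate 2's list but not in replicate 1's, and Vsx2 and Gfap in replicate 1's but not in replicate 2's. Both lists marked 14480 genes and neither marked 6769. Replicate 1 alone marked 377 genes, at a median signal value of 2.99 against 14.9 for all genes marked in its list. Replicate 2 alone marked 285 genes, at 2.90 against 12.9 for all genes marked in its list. The calls were the same for 97.0% of genes (95% Wilson interval 96.7 to 97.2), with Cohen's kappa of 0.931.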

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

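No test in this part was chosen after its result was seen. The comparisons left out 11 replicated H3K9ac peaks on scaffolds outside chromosomes 1 to 19, X and Y. That is above the 3 peaks that a count of 0 allows, but no control peak list was at hand, so the count does not show that these peaks stand above background. The authors' own values for each peak are already set against the control. Of these 11 peaks, 5 lay on a scaffold assigned to chromosome X and 1 on a scaffold assigned to chromosome 4, and 5 on unplaced scaffolds. The replicates' own lists had 14 and 13 peaks on scaffolds. No gene list used these positions, and no biological explanation was tested.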

How the results depend on the processing

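Alternatives chosen only after the data were seen were replicated peaks that overlap both replicates' own peaks, genes sharing a TSS window left out, and each domain counted once. No paired analysis was possible because the design has 1 group. The overlap of the replicates' peaks stayed above its shifts under every alternative run, from 35.2% (50% of both peaks) to 53.4% (1 bp) in replicate 1 and from 40.8% to 59.7% in replicate 2. Joining touching peaks moved nothing in these comparisons, since no list holds touching peaks, so it tests nothing there. Overlap, strength and gene calls of single replicates need both replicates, so no replicate could be left out. The neural tube class stayed above the other tissue class, and Hox groups 1 to 9 above forebrain and midbrain factors, under every alternative run.

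Peak strength and replication moved with the overlap: Spearman's rho was 0.751 with 1 bp and 0.907 with 50% of both peaks, and the top minus bottom bin was 68.0 and 80.2 points. The share of peaks in other exons fell below its shifts when any overlap of 1 bp set the class (6.98%), where a peak counts first as TSS. The share in introns exceeded the mean of its shifts in place of falling below it with the pooled list (44.8%), and without either replicate in turn (39.9% to 41.5%), where only the share without replicate 2 differed from its shifts. With the 500 bp window it did not differ from them (41.3%). Promoters marked were 65.7% with 500 bp, 67.2% with 2 kb, 62.7% with the 5′ end only, 69.1% with the pooled list, 65.6% with peaks overlapping both replicates' own peaks and 67.4% to 67.8% without either replicate. With genes sharing a TSS window left out, the share was 61.6% (11240 of 18259). The window, TSS and stricter-peak changes allow more or fewer peaks by construction. For the other values above, the cause was not tested.

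With CpG-rich TSS windows only, 0 gene lists were marked more often and 3 less often, since 99.0% of such genes were marked. When only touching peaks were joined, 8 lists had wider domains. The number of lists with narrower domains was 4 with the 2 kb window, 4 with the pooled list, 1 with each domain counted once and 5 without either replicate (5 to 5). Gene calls of the replicates were the same for 97.2% of genes with a −log10 q of at least 2, with a kappa of 0.938. For the narrower lists and the gene calls, the cause was not tested.

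Several lists crossed the share or the median of other genes. With CpG-rich windows only, the share marked was 90.0% for ventral patterning, 96.4% for spinal subtypes, 88.9% for Hox groups 10 to 13, 91.7% for neural crest and 100% for glial, erythroid and skin genes. These are set against 99.0% of CpG-rich genes. Ventral patterning was at 66.7% without either replicate (66.7% to 66.7%). Glial genes were at 70.0% with 2 kb, 75% with the pooled list, 63.2% without genes sharing a TSS window and 70.0% to 75% without either replicate. Endothelial genes were at 61.1% with the 5′ end only and 66.7% without replicate 2 (88.9% without replicate 1), and muscle genes at 72.0% with 2 kb and 72.0% without replicate 1 (56.0% without replicate 2). Median widths crossed the random median for proneural genes joined across 3 kb (2811 bp), endothelial genes without replicate 2 (2411 bp, against 1437 bp without replicate 1) and S phase genes. S phase genes had 2320 bp with 2 kb, 2291 bp with the 5′ end only, 2268.5 bp with peaks overlapping both replicates' own peaks and with each domain counted once, 2697 bp across 3 kb and 2202.5 to 2377.5 bp without either replicate. For these lists, the cause was not tested.

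Of the other list values, 245 shares and 238 widths stayed on their side of the test's threshold and kept their direction, counting each list under each alternative. Among shares 15 lost a call and 11 gained one, and among widths 17 lost a call and 8 gained one. Read depth is unknown, so its limit on weak peaks was not measured.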

Other observations

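Tests chosen only after the result was seen were those of gene families, of base composition and of 1 active X chromosome, of the detection limit, of pool differences and of list lengths as the whole cause, and of internal start sites and keratinocyte genes. Gene families picked by symbol, some of which share members with the fixed lists, ranged from all marked to none marked. Sox genes (19 of 19), glutamate receptors (24 of 24), subunits of NADH dehydrogenase (46 of 46) and mitochondrial ribosomal proteins (78 of 78) were all marked. Wnt ligands were marked in 18 of 19 cases, with Wnt8a unmarked, and forkhead genes in 36 of 44, with Foxg1, Foxn4 and Foxe1 among the unmarked. Vomeronasal receptors were marked in 1 of 326 cases (Vmn1r4), bitter taste receptors in 0 of 35, beta defensins in 0 of 42 and keratins in 6 of 49. Clustered protocadherins, though neuronal, were marked in only 15 of 56 cases (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 24 families, p = 4.66e-09). Irx and Dlx genes were marked in 6 of 6 cases each, with median domains of 5024.5 and 630 bp that no test compared. Neither family was called (adjusted exact p = 0.197 each), and replicate 1's own list marked 5 Dlx genes. LIM homeobox (8 of 8), GABA-A receptor (14 of 19) and Tbx genes (6 of 13) were not called either.

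The CpG-rich genes without a replicated peak, looked at after the lists were tested, were few. They numbered 76, and 59 of them had no peak at the TSS in either replicate's own list. Of the 76, 11 came from the forebrain and midbrain list: Emx2, Eomes, Fezf1, Fezf2, Foxg1, Nkx2-1, Nr2e1, Otx1, Otx2, Rax and Six3. Dbx1 and Wt1 of the ventral and spinal lists, Hand2, Cdx2, Gata4, Hnf1b, Pax9, T, Hoxa13 and the germline genes Ddx4 and Sycp1 were among the others. An enrichment test of this group for transcription factor families taken by symbol was run once and dropped after its result was seen, because the symbol pattern was chosen late and also took in unrelated genes such as Entpd4. It is not reported, and no claim of enrichment is made. Several multi-copy histone genes were among them as well, and near-identical copies leave such calls uncertain.

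Promoters on chromosome X had lower signal values than autosomal ones. Matched on CpG class and GC content, the X to autosome ratio of the medians was 0.679 in the replicated list. Its upper 95% bootstrap bound of 0.719 lay below 0.9, which argues against base composition as the whole cause. Ddx3x, Kdm5c, Kdm6a and Eif2s3x, which escape X inactivation, had a median of 19.9 against 9.75 for 463 other X promoters. The one-sided permutation p was 0.0001, the smallest that 10000 permutations can give. These 4 genes were picked by name and not matched to the others on promoter activity. The test therefore cannot tell escape from a strong promoter, and it decides nothing on copy number alone. Among CpG-rich X promoters alone, 145 others had a median of 11.5 (one-sided permutation p = 0.0012). With 1 active X per cell as a candidate explanation the test stayed open, since the higher upper bound in the replicates' own lists was 0.759, above the 0.75 set for it. That limit was set after the data were seen. It was not shown to separate 1 active X from X copy number in embryos pooled over both sexes, so it decides nothing on either. Replicated peaks were also sparser on X, at 5.27 per Mb against 12.3 to 35.1 on autosomes. Of pooled peaks on X, 75.2% were in the replicated list, against at most 48.6% on an autosome. The pooled list held 1145 peaks on X and replicate 1's own list 1166, whereas on every autosome the pooled list held more. The cause of these differences between lists was not tested, and beyond X copy number and 1 active X no biological explanation was tested.

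Many peaks of each replicate lacked a partner in the other, 46024 in replicate 1 and 36248 in replicate 2. Of these peaks at most 0.115% lay in the top signal bin, where 20% would lie with no relation to strength, so peaks near the detection limit may account for the pattern. The shares by bin had been seen before, so this is no independent test. Only 0.0587% of replicate 1's top-bin peaks and 0 of replicate 2's were untouched by the other list, so strong peaks, which the shares by bin already showed to be paired, hardly enter the pattern. Taking as many top peaks from each list raised replicate 1's share by 4.60 points, but it could have raised it by 7.34 at most, so the 20 points set for this test decide nothing. With lists of the same length, 49.5% of peaks still lacked a partner in the replicate with the lower share, which argues against unequal lengths as the whole cause. Differences between the pools at weak peaks stay open, as untested.

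Krt1, Krt10 and Lor, genes of the skin's surface, were marked in a neural tissue. Their peaks had signal values of 13.6, 14.4 and 13.5 and covered exons for 93.2%, 52.6% and 81.8% of their length. None of 11 other keratinocyte genes such as Krt5, Krt14 and Trp63 was marked (0 of 11), which argues against keratinocytes in the tissue. Krt5, Krt14, Krt15, Trp63, Dsg3 and Dsg1a were in the skin list, whose calls had been seen, so this is no independent test. The skin list as a whole was marked in 9 of 20 cases. Repeated sequence under the peaks stayed a candidate: their shares of recurring 12-mers lay at or above the 95.5th percentile of replicated peaks of like width. The compared peaks were matched on width and not on exon content. The test therefore cannot tell repeats as a cause from the exons that these peaks cover. Start sites of internal transcripts stayed open, since 1 of the 3 genes (Lor) had a peak within 1 kb of its 5′ end.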
